A study of Caenorhabditis elegans with 18 samples.

How the data were processed

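The series measured messenger RNA of whole Caenorhabditis elegans, wild-type strain N2, on Affymetrix C. elegans arrays with 1 colour. Per the labels' protocols, cultures of 10 ml held 10000 larvae, hatching spanned 2.5 h, RNA was extracted with TRIzol, and 100 ng of RNA was amplified and biotin labelled for each array. The labels name 18 conditions, and the array information files hold 3 arrays for each, 54 in all, from 3 culture series. The authors' deposited tables hold 1 mean per condition, so any spread between cultures could enter only through their error and test columns. Each GEO sample was treated as 1 sample.

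Expression values are intensity on a linear scale, given by the authors as the mean of 3 biological replicates per condition, per the read-me and the notes in the deposited tables. Values below 5 were raised to 5 per those notes. The software, background method and between-array normalization are not given in the sources used here. The deposited error table is an intensity in the same unit, described by the authors' read-me as the experimental error of each mean. Scaled by it, the M9 minus S-complete differences had a root mean square near that of a standard error of the mean, so it was used as one. Near-equal means could carry near-equal errors, such as adh-1 in starved larvae at 3 h (5346 ± 653) and 24 h (5341 ± 653). Others did not, such as fmo-2 in starved larvae at 1 h (852 ± 104) and 6 h (894 ± 266). The error therefore need not measure the spread between cultures. The deposited detection table was treated as a score: per the file headers it is a p of the probe set signal against background, and the authors called a probe set detected under 1e-10. The authors' p-value tables hold tests between pairs of conditions and 1-factor and 2-factor analyses of variance, per the file headers; the scale of the values they tested is not given. The deposited series matrix holds the same means rounded to whole numbers, within 0.5 of the mean table. The array information files gave hybridization days, which were counted but not printed.

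Of 22625 probe sets, 77 controls were left out, which left 22548 worm probe sets. The deposited annotation maps probe sets to WormBase release 180: 20319 mapped to a single gene, 290 were not unique and 1939 had no mapping. Names were updated through a RefSeq gene table (assembly WBcel235) and the platform annotation, and 19978 of the unique probe sets had a current symbol. Of these, 597 were named through the platform annotation, 11 carried a name since given to another gene and were renamed, and 341 unique probe sets had no current match. For 216 the sources named different genes, and these were not named as leading genes. The renaming step was added after values had been seen, when the older name icl-1 was found to stand for a chloride channel regulator and the isocitrate lyase gene was listed as gei-7. The gene listed as sodh-1 is printed as adh-1. No coordinates are given because no annotation of the authors' build was used. For gene lists the probe set with the highest mean was used for each of 17465 genes, and 17375 of these were the authors' primary or only probe set for the gene.

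Log2 of the deposited means was tested without a pseudocount, since the floor is 5. The fed against starved comparison over 7 matched times used limma (lmFit and eBayes) on the 14 fed and starved S-complete conditions, with time as a factor; its residual is the change of the food difference between times, not array error. The growth of the difference was the slope on log2(h + 1) in a model with time and food. The Benjamini-Hochberg method was applied over 22548 probe sets with a threshold of 0.05. Pairs of conditions used the authors' p-values for that pair, adjusted here in the same way, with the direction from the means. Differences between 2 conditions carry an error propagated from the authors' errors; the recomputed test divided the difference of the linear means by their combined errors, with 4 degrees of freedom from 3 arrays per mean. Gene lists were tested with camera (preset correlation 0.01), adjusted over the lists, and with fry, which tests whether members move 1 way on balance. In pairs of conditions the median of a list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Members of a list can move together and random lists do not keep this correlation, so the percentiles can overstate how far a list was displaced. With fry the unadjusted p was 0.000827 for the proteasome, 0.000492 for autophagy, 0.0193 for moulting and 0.25 for collagens. With a correlation estimated from the data, none of the camera calls of the 7-time comparison held.

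Genes were named by a rule fixed before the data were examined, as were the lists, the tests and the alternatives. The rule takes probe sets past the threshold, with the same sign at 7 of 7 times in the 7-time comparison, mapped to 1 gene with a public name and detected in the higher condition, ranked by size: the 10 highest and 10 lowest in the 7-time comparison and the 6 highest and 6 lowest elsewhere, with at most 2 per gene class. Where nothing passed, genes were ranked by size alone. Detection in the higher condition was read as detection at 4 or more of the 7 times, a number set later. The rule adds the 2 to 4 members of each list with the largest difference past the threshold and 25 genes always given. The lists, from textbook knowledge, were cytosolic ribosomal proteins, ribosome biogenesis, translation factors and tRNA synthetases, DNA replication and cell cycle, histones, DAF-16 targets, heat shock and unfolded protein response, detoxification, glyoxylate cycle with gluconeogenesis and trehalose, fatty acid oxidation, fatty acid synthesis, mitochondrial respiratory chain, autophagy, proteasome, collagens, moulting, heterochronic timing, insulin-like peptides, TGF-beta and dauer signalling, digestive enzymes, lysozymes and antimicrobial peptides, and vitellogenins, with markers of muscle, pharynx, neurons, intestine, hypodermis, germ line and early embryo.

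The fits and a test of a pair were tried on simulated data with 50 changed genes per size among 22548. The 7-time fit recovered 20%, 70% and 96% of genes changed by a log2 of 0.5, 1 and 2 and 62% at -1, with 8 false calls (6.06% of its calls). The slope fit recovered 20% and 56% at slopes of 0.3 and 0.6 and 6% and 48% at -0.3 and -0.6, with 2 false calls. In both, the noise was independent between probe sets and conditions, and far fewer genes changed than the 7-time fit called in the data. The changed genes were all detected ones. The recovery and false calls need not carry over to the real fits. A pair test that used the sample variance of 3 simulated arrays recovered 0%, 4% and 12% at 1.5, 2 and 4-fold and 6% at 0.5-fold, with 0 false calls. The recomputed test divides by the authors' errors instead, so these values do not give its power. The authors' own pair test could not be simulated, so its power is not known. The alternatives were quantile normalization, detected probe sets alone, the series matrix values, an intensity trend, each time left out, no time factor, linear hours, other thresholds for pairs of conditions, recomputed p-values, another reference for the switches, an estimated correlation and the mean of all probe sets of a gene. A contrast of fed 3 h with M9 3 h larvae, which share hybridization days, was added after the results were seen. The embryo, M9 and switched conditions were left out of the 7-time fit because they have no fed and starved pair. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.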

Results

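Gene expression was measured on Affymetrix C. elegans arrays in whole animals of the wild-type Caenorhabditis elegans strain N2. Larvae hatched into S-complete, a buffered liquid medium, either with the bacterium Escherichia coli HB101 at 25 mg/ml as food or without food, at 20 °C. Larvae that hatch without food stop developing in the first larval stage and can resume growth when they are fed. The design asks how expression differs with food over time after hatching, and what happens when food is given or taken away. There were 18 conditions, each measured on 3 arrays from 3 culture series, 54 arrays in all. Fed and starved larvae were collected at 0, 1, 3, 6, 12, 15 and 24 h after hatching, where 0 h was the time at which 50% of the embryos had hatched. The sample titles give the larvae as L1, the first larval stage, except fed larvae at 15 h (L1 to L2) and 24 h (L2), so stage differed with food at these times. The other conditions were embryos 2 h before hatching, larvae starved for 3 h in M9 buffer, larvae starved for 12 h and then fed for 3 h, and larvae fed for 12 h and then starved for 3 h. The values used were the authors' mean and error for each condition, so each condition counted as 1 sample, and errors on differences between conditions were propagated from the authors' errors. The median intensity of a condition lay between 35.3 and 41.5, and the authors' detection threshold was passed by 10873 (M9) to 12332 (fed 12 h) of the 22548 worm probe sets. Over detected probe sets the median error was 8.82% to 10.7% of the mean. These errors need not measure the spread between cultures, and the number of arrays limits precision.

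Across the 7 matched times, fed larvae had lower levels of a set of genes that were detected at 4 or more of these times in starved larvae. The linker histone-like gene hil-1 was lower in fed larvae by a log2 difference of -4.30 ± 0.39 (SE; limma adjusted p = 0.00123), and far-7, which encodes a fatty acid and retinol binding protein, by -4.25 ± 0.31 (adjusted p = 0.00072). The flavin monooxygenase fmo-2 was lower by -3.77 ± 0.13 (adjusted p = 0.000113). The cathepsin B-like protease cpr-2 (-3.51), the glutamate-gated chloride channel glc-1 (-3.36), the ammonium transporter amt-1 (-3.18), the alcohol dehydrogenase adh-1 (-3.16), the nicotinamide nucleotide transhydrogenase nnt-1 (-3.05), the trypsin-like protease try-12 (-3.03) and the sulfate permease family member sulp-5 (-2.93) were also lower. In the other direction, the invertebrate lysozyme ilys-5 was higher in fed larvae by 4.98 ± 1.08 (adjusted p = 0.0156), followed by dbd-20 (4.93), abu-10 (4.12), the carnitine palmitoyltransferase family member cpt-4 (4.08), the astacin protease nas-38 (3.98) and phg-1 (3.96). The hedgehog-related genes grl-7 (3.95) and grd-14 (3.78), abu-14 (3.87) and the cuticle collagen col-109 (3.74) completed the 10 most strongly raised genes. The rule for naming genes required the same direction at 7 of 7 times. For cpr-2 the direction at 0 h rested on 14.95 in starved and 14.65 in fed larvae, neither of them detected.

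In this comparison limma, with time as a block, called 6831 of 22548 probe sets, 3054 higher and 3777 lower in fed larvae, and 9556 had an unadjusted p under 0.05. The fit took the 7 times as independent pairs, but all arrays came from 3 culture series and a food difference can carry over between neighbouring times. Its errors, p-values and counts, and those of the slope with time, may therefore overstate certainty. For 17 of the 20 named genes the authors did not detect the probe set in at least 4 of the 7 lower conditions, so the size of the difference rests on a level near background. Several calls depended on single times: cpr-2 was not past the threshold without 6 h (-3.36), 12 h (-3.22), 15 h (-3.20) or 24 h (-3.10). The same held for grl-7 without 12 h (3.35), 15 h (3.71) or 24 h (3.40) and for col-109 without 3 h (3.80), 12 h (3.47) or 15 h (3.31). The array files put the fed and the starved S-complete arrays on 3 hybridization days each, with 0 days in common. Day and food were therefore not separable in this fit. The M9 arrays of starved larvae shared the days of the fed arrays. In the fed 3 h minus M9 3 h difference, where the medium differed too, 18 of the 20 named genes kept their sign. Examples were hil-1 (-4.01 ± 0.47), far-7 (-3.71 ± 0.27) and, less precisely, grd-14 (1.72 ± 0.98), while fmo-2 (2.34 ± 1.16) and adh-1 (0.14 ± 0.38) did not. The naming rule had already used fed 3 h, so this agreement is partly built in. The fed minus starved 12 h difference shares no condition with the fed 3 h minus M9 3 h difference. Across probe sets they correlated with a Pearson r of 0.4815. Of the 2230 probe sets called at 12 h, 85.3% had the same sign in both.

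Lists of protein turnover and protein synthesis had more members higher than lower in fed larvae, to different extents. Of 33 proteasome genes 31 were higher and 0 lower (32 and 0 adjusted over the list alone), with a median of 0.76 and a camera adjusted p = 7.15e-14, and adjusted p = 0.44 with an estimated correlation. They included the core subunits pas-7 (1.75) and pas-5 (0.95) and the regulatory subunits rpn-12 (1.09) and rpn-9 (1.03). Translation factors and tRNA synthetases had 36 of 57 members higher and 0 lower (37 and 0 adjusted over the list alone), among them eif-3.H (2.06), inf-1 (1.41), eif-3.C (1.09) and the lysyl-tRNA synthetase kars-1 (1.03), with a median of 0.51 and adjusted p = 4.34e-10, or adjusted p = 0.44 with an estimated correlation. Of 30 ribosome biogenesis genes 15 were higher and 0 lower (19 and 2 adjusted over the list alone), with nol-14 at 1.19, the nucleolar methyltransferase fib-1 at 1.06, nol-58 at 1.06 and the RNA polymerase I subunit rpoa-2 at 0.86. The median of this list was 0.55 (adjusted p = 0.000251, and adjusted p = 0.587 with an estimated correlation). Chaperones of the heat shock and unfolded protein response had 13 of 24 members higher and 0 lower (14 and 1 adjusted over the list alone), led by hsp-12.1 (2.53), the mitochondrial chaperonin hsp-60 (1.64), the endoplasmic reticulum chaperone hsp-4 (1.61) and hsp-17 (1.45). Their median was 0.71 (adjusted p = 3.35e-05, and adjusted p = 0.44 with an estimated correlation). The 80 cytosolic ribosomal protein genes stayed close together, with a median of 0.03, 5 higher and 1 lower (1 and 0 adjusted over the list alone), such as rps-20 (0.27), rpl-26 (0.22) and rsl-24D1 (-0.93), which encodes a ribosome assembly factor despite its older ribosomal protein name. The adjusted p of that list was 0.00396, with adjusted p = 0.44 with an estimated correlation, 0.525 after quantile normalization and 0.172 over detected probe sets.

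Lists of moulting, DNA replication and histone genes had more members higher than lower, and collagens were mixed. Of 80 moulting genes 29 were higher and 1 lower (33 and 1 adjusted over the list alone), including nas-38 (3.98), grd-14 (3.78), mlt-8 (3.73) and wrt-10 (3.65), with a median of 0.94 (adjusted p = 9.3e-06, and adjusted p = 0.582 with an estimated correlation). Collagens had 14 of 160 members higher and 8 lower (3 and 6 adjusted over the list alone) and col-109 (3.74), dpy-7 (3.26), col-113 (3.20) and dpy-3 (3.18) at the top. Their median was 0.34 (adjusted p = 0.00123, and adjusted p = 0.742 with an estimated correlation). The call of dpy-7 was not kept without 1 h (3.41), 6 h (3.06), 12 h (2.74), 15 h (3.45) or 24 h (2.63). DNA replication and cell cycle genes had 12 of 65 members higher and 0 lower (11 and 0 adjusted over the list alone), with klp-18 (1.37), psf-2 (1.02), the Aurora kinase air-1 (0.98) and psf-1 (0.89), a median of 0.24 and adjusted p = 0.00123, or adjusted p = 0.742 with an estimated correlation. At single times the median of this list was 0.82 at 3 h but -0.35 at 15 h and -0.34 at 24 h, so its sign depended on time. Histones had 19 of 48 members higher and 2 lower, as also when adjusted over the list alone, including his-29 (0.97), his-62 (0.79) and his-48 (0.79). Their median was 0.29 (adjusted p = 0.000196, and adjusted p = 0.587 with an estimated correlation), and near-identical copies of histone genes share probe sequence.

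Of 3 further lists, autophagy, targets of the FoxO transcription factor DAF-16, and glyoxylate cycle with gluconeogenesis and trehalose, more members were lower than higher in fed larvae. Of 27 autophagy genes 17 were lower and 0 higher (18 and 0 adjusted over the list alone), with lgg-2 at -1.28, atg-18 at -1.09, atg-13 at -1.01 and atg-16.2 at -0.93. Their median was -0.47 (adjusted p = 9.53e-07, and adjusted p = 0.44 with an estimated correlation). The list of DAF-16 class I targets and longevity-associated genes had 16 of 33 members lower and 1 higher (19 and 1 adjusted over the list alone), with adh-1 (-3.16), nnt-1 (-3.05), the superoxide dismutase sod-3 (-2.65) and dod-3 (-2.58). Its median was -0.34 (adjusted p = 1.14e-05, and adjusted p = 0.083 with an estimated correlation). Genes of the glyoxylate cycle, gluconeogenesis and trehalose had 7 of 20 members lower and 1 higher (8 and 1 adjusted over the list alone), with adh-1, the trehalose synthase tps-1 (-1.31) and the pyruvate carboxylase pyc-1 (-0.72) lower and gpdh-1 (2.37), which makes glycerol 3-phosphate, higher. The median was -0.42 (adjusted p = 0.00396, and adjusted p = 0.44 with an estimated correlation).

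Germ line markers had 7 of 20 members higher and 0 lower (9 and 0 adjusted over the list alone), with car-1 (1.26) and pgl-1 (1.22) highest, followed by glh-1 and the Notch receptor glp-1, a median of 0.40 and adjusted p = 0.0244. Neuronal markers had 6 of 17 members lower and 1 higher (7 and 1 adjusted over the list alone), with egl-3 (-0.63), egl-8 (-0.59) and unc-13 (-0.56) lower and tbb-4 (0.69) higher, a median of -0.28 and adjusted p = 0.0244. For both lists the value was adjusted p = 0.715 with an estimated correlation, and 0.0636 over detected probe sets. Pharyngeal markers had 4 of 10 members higher and 0 lower, as also when adjusted over the list alone, with pqn-26 (2.04), phat-1 (1.81) and the myosin light chain mlc-5 (0.29), a median of 0.28 and adjusted p = 0.0318. The pharynx value was adjusted p = 0.715 with an estimated correlation, and the call was not kept without 15 h (0.124) or 24 h (0.0714), nor was the neuronal call without 24 h (0.0607). Intestinal markers had 4 of 14 members higher and 2 lower (5 and 2 adjusted over the list alone; adjusted p = 0.206), with pgp-1 (2.28), pgp-3 (1.11) and act-5 (0.97) higher and the esterase ges-1 (-1.36) lower. Body wall muscle had 0 of 15 members higher and 4 lower, such as mlc-1 (-0.55) and the myosin myo-3 (-0.53), with adjusted p = 0.306. Hypodermal markers had 2 of 10 members higher and 2 lower, as also when adjusted over the list alone (adjusted p = 0.628), with wrt-2 (2.76) higher and elt-3 (-0.75) lower. Early embryo markers had 1 of 15 members higher, skn-1 (0.44), and 1 lower, pal-1 (-0.48), with 0 and 0 adjusted over the list alone and adjusted p = 0.544.

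Several lists did not pass the camera test while single members differed in opposite directions. Fatty acid oxidation and lipolysis had 8 of 42 members higher and 7 lower (10 and 9 adjusted over the list alone; adjusted p = 0.175), with ech-1.1 (2.65) and acdh-2 (2.26) higher and the lipase lipl-3 (-3.04) lower. Fatty acid synthesis and desaturation had 4 of 20 members higher and 4 lower (4 and 5 adjusted over the list alone; adjusted p = 0.606), with the stearoyl-CoA desaturase fat-7 (3.07) and the acyltransferase dgat-2 (1.83) higher and the desaturase fat-4 (-1.24) and the mediator subunit mdt-15 (-1.09) lower. The median of that list was -0.24 and its mean 0.02, so the sign differed while the test pointed down. Detoxification genes had 31 of 185 members higher and 47 lower (36 and 51 adjusted over the list alone; adjusted p = 0.526), from cyp-35C1 (3.22) and ugt-8 (2.83) to cyp-32B1 (-3.05) and cyp-37B1 (-3.87). Lysozymes and antimicrobial peptides had 11 of 61 members higher and 8 lower (12 and 8 adjusted over the list alone; adjusted p = 0.103), with cnc-4 (3.38) and spp-23 (3.21) higher. Digestive enzymes had 2 of 38 members higher and 9 lower, as also when adjusted over the list alone (adjusted p = 0.606), including asp-13 (-1.26) and the nuclease nuc-1. TGF-beta and dauer signalling had 2 of 19 members higher and 7 lower (2 and 9 adjusted over the list alone; adjusted p = 0.0813), with daf-36 (2.56) and lon-1 (1.78) higher and daf-5 and sma-2 (-1.19) lower. Insulin-like peptides had 2 of 24 members higher and 3 lower (2 and 2 adjusted over the list alone; adjusted p = 0.635), with ins-6 (1.17) higher and ins-24 (-1.47), ins-35 (-1.30) and ins-17 (-1.15) lower. Heterochronic genes had 2 of 13 members higher and 0 lower, as also when adjusted over the list alone (adjusted p = 0.496), lin-42 (2.67) and the Argonaute alg-2 (0.76). The mitochondrial respiratory chain had 5 of 42 members higher and 7 lower, as also when adjusted over the list alone (adjusted p = 0.312), with asb-1 (0.84) and ucr-2.3 (0.49) higher and ucr-2.1 (-0.42) lower. Of the 6 vitellogenins limma called 0, over all genes and adjusted over the list alone (adjusted p = 0.191).

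Among genes of insulin signalling and developmental timing, daf-16 was lower in fed larvae by -0.66 (adjusted p = 0.00447), and the stress genes hsp-12.6 (-2.49, adjusted p = 0.00275) and the metallothionein mtl-1 (-2.35, adjusted p = 0.00319) were lower with sod-3 (adjusted p = 0.00105). The Period homologue lin-42 (adjusted p = 0.0145), fat-7 (adjusted p = 0.00533), fib-1 (adjusted p = 0.0113), dpy-7 (adjusted p = 0.0446) and the insulin-like gene ins-7 (0.78, adjusted p = 0.022) passed in the other direction. The call of ins-7, which was detected in 0 conditions, was not kept without 6 h (0.74), 12 h (0.77) or 15 h (0.72). The acyl-CoA synthetase acs-2 (-3.16, adjusted p = 0.0643), the isocitrate lyase and malate synthase icl-1 (-1.13, adjusted p = 0.0519), the cyclin-dependent kinase inhibitor cki-1 (-0.36, adjusted p = 0.0528) and daf-28 (0.78, adjusted p = 0.0777) missed the threshold. Leaving out 0 h brought acs-2 (-3.90), icl-1 (-1.35) and daf-28 (0.95) past it, as did leaving out 1 h for acs-2 (-3.83), and 12 h (-0.43) or 15 h (-0.42) for cki-1. Testing detected probe sets alone also brought these 4 genes past it, as did quantile normalization and no time factor for icl-1 and cki-1 and an intensity trend for icl-1. Other genes named in advance did not pass: the insulin receptor daf-2 (-0.23, adjusted p = 0.244), lin-35 (0.07, 0.822), lin-14 (-0.28, 0.0935), lin-28 (-1.08, 0.138), hbl-1 (-0.08, 0.862), the moulting regulator nhr-23 (0.47, 0.17) and mlt-10 (1.65, 0.172). Of these daf-2 passed without 12 h (-0.35) and lin-14 without 3 h (-0.36), and both were detected in 0 conditions. The replication genes pcn-1 (0.32, adjusted p = 0.266) and rnr-1 (0.06, 0.764), the ribosomal protein gene rpl-3 (0.01, 0.882), the elongation factor gene eft-3 (-0.03, 0.561) and the myosin gene unc-54 (0.08, 0.729) did not pass either.

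**Figure D1:**
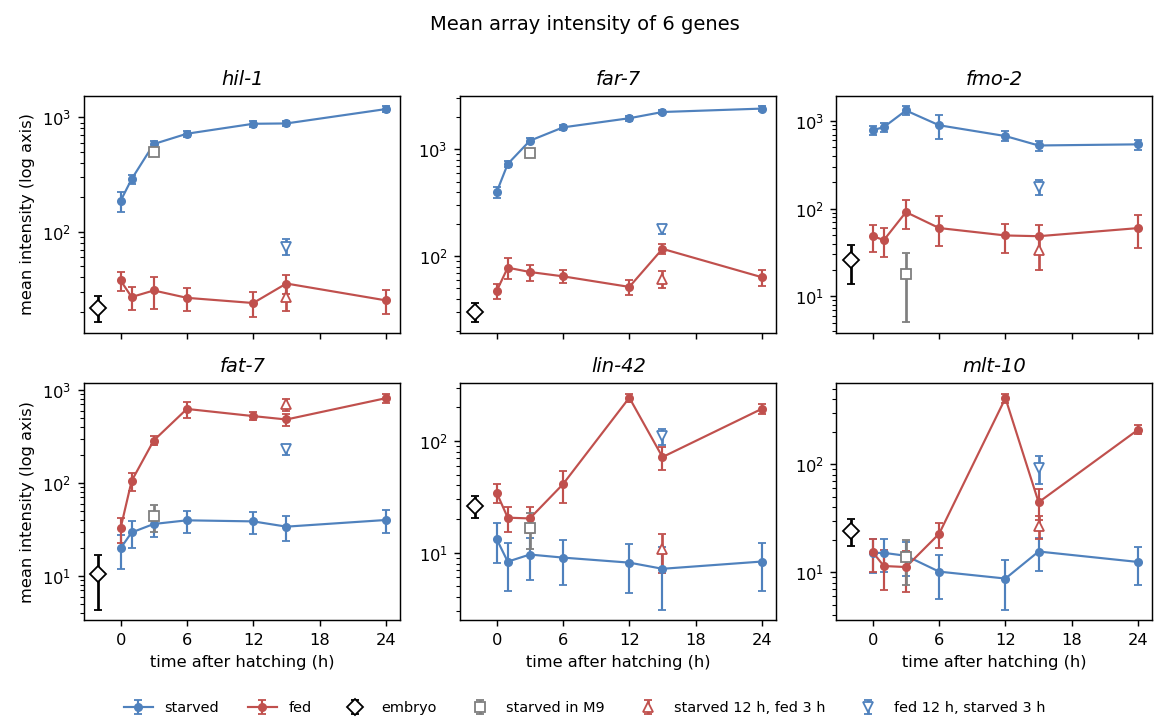
Authors' mean intensity (log axis, bars show the authors' error) against time after hatching in h for hil-1, far-7, fmo-2, fat-7, lin-42 and mlt-10 in fed and starved larvae, with separate markers for the embryo, M9, refed and starved-after-feeding conditions. At 24 h hil-1 stood at 1180 in starved and 25.3 in fed larvae, and lin-42 in fed larvae stood at 245, 71.9 and 195 at 12, 15 and 24 h.

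The fed minus starved difference also changed with time for some genes. Per unit of log2(h + 1), the difference rose by 1.75 ± 0.19 (SE) for ilys-5, 1.59 for irg-5, 1.57 for irg-4, which are infection response genes, 1.57 for the glucuronosyltransferase ugt-22, 1.48 for the prolyl carboxypeptidase-like gene pcp-2 and 1.41 ± 0.10 for the arginine kinase argk-1 (limma adjusted p = 0.0073). It became more negative for cpr-2 (-1.39 ± 0.10, adjusted p = 0.0073), math-28 (-1.11), the C-type lectins clec-76 (-1.06) and clec-15 (-0.97), fbxc-51 (-0.98) and amt-1 (-0.90). Limma called 1214 probe sets, 483 with a rising and 731 with a falling difference. The count depended on every time: it was 185 without 0 h, 26 without 1 h, 698 without 3 h, 764 without 6 h, 511 without 12 h, 632 without 15 h and 191 without 24 h. Of the 12 named genes, argk-1 and cpr-2 kept their call whichever time was left out, but cpr-2 lost it with linear hours (-0.237 per h). Without 1 h the calls of ilys-5 (1.78), irg-5 (1.61), ugt-22 (1.53), irg-4 (1.53), pcp-2 (1.43), math-28 (-1.03), clec-76 (-1.02), fbxc-51 (-0.95), clec-15 (-0.94) and amt-1 (-0.83) were lost. The authors did not detect the probe set in at least 4 of the 7 lower conditions for 10 of these 12 genes.

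At single times, the earliest larvae differed least. At 0 h the authors' deposited p-values, adjusted here over all worm probe sets, called 0 probe sets, with 1421 at an unadjusted p under 0.05, and a test recomputed from the means and errors also called 0. By size alone, fmo-2 (-4.01 ± 0.52), far-7 (-3.08 ± 0.28), scl-14 (-2.57), the collagen col-98 (-2.54), the cathepsin B-like gene cpr-6 (-2.48) and slc-36.3 (-2.38) were lower in fed larvae. In the other direction skpo-2 (3.45), bigr-1 (3.32), bus-24 (3.10), dct-5 (2.99), dhs-8 (2.81) and lgc-22 (2.71) were higher. The authors did not detect 10 of these 12 genes in the lower condition. At 1 h the deposited p-values called 1 probe set, the proton and myo-inositol transporter hmit-1.3, which was lower in fed larvae by -1.08 ± 0.14, with 3228 at an unadjusted p under 0.05, and the recomputed test called 0. Among the list medians displaced from random lists of the same size at 0 h were translation factors (0.12), proteasome (0.23), heat shock (0.31), DAF-16 targets (-0.32) and glyoxylate and trehalose genes (-0.34). Autophagy (-0.12) was not displaced at 0 h. At 1 h these medians were all displaced: translation factors 0.47, proteasome 0.45, heat shock 0.60, autophagy -0.46, DAF-16 targets -0.45 and glyoxylate and trehalose genes -0.58. In these lists 0 members were called over all genes at 1 h. Adjusted over the list alone, 3 translation factors, 2 proteasome and 4 heat shock genes were higher at 1 h and 1 heat shock, 6 autophagy, 4 DAF-16 and 6 glyoxylate genes lower. Other medians lay above random lists at 0 h, with moulting (0.42) the highest of all lists. They were germ line (0.34), early embryo (0.28), histones (0.17), DNA replication (0.10) and collagens (0.09), while TGF-beta and dauer signalling (-0.28) lay below. Random lists do not share the correlation between members of a list, so displacement can be overstated.

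At 3 h the desaturase fat-7 was higher in fed larvae by 2.98 ± 0.44, dgat-2 by 2.66 ± 0.40, the phosphatidylcholine synthesis gene pcyt-1 by 2.56 ± 0.30, ugt-16 by 2.11, the carnitine synthesis gene gbh-1 by 1.90 and the fatty acid elongase elo-2 by 1.83. Lower were far-7 (-4.08 ± 0.26), dlhd-1 (-3.20), dod-3 (-2.97), sulp-5 (-2.92), cpr-2 (-2.87) and the dehydrogenase dhs-31 (-2.64). Of the DNA replication and cell cycle genes, 4 were called higher over all genes and 26 adjusted over the list alone, including the kinase cdk-1 (1.45), cyk-4 (1.12), rnr-2 (0.90) and orc-2 (0.49), and the list median of 0.82 lay at the 100th percentile of 10000 random lists. Ribosome biogenesis (median 0.96, 1 called and 11 adjusted over the list alone), translation (0.86, 2 and 28) and proteasome genes (0.78, 1 and 29) lay at the same percentile. DAF-16 targets (-0.64), autophagy genes (-0.55) and collagens (-0.35) lay at the bottom. The deposited p-values called 232 probe sets, 94 higher and 138 lower, with 4853 at an unadjusted p under 0.05. A test recomputed from the deposited means and errors called 0 at 3 h. The authors did not detect 9 of the 12 leading genes in the lower condition.

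At 6 h the acyl-CoA oxidases acox-1.2 and acox-1.3 were higher in fed larvae by 4.39 ± 0.43 and 3.10 ± 0.33, pugs-2 by 3.76, mpst-7 by 3.21, the procollagen lysyl hydroxylase let-268 by 2.99 and the intermediate filament gene mua-6 by 2.95. Lower were far-7 (-4.63 ± 0.21), svct-1 (-3.78), the glutamate transporter glt-5 (-3.60), the glycerol channel aqp-1 (-3.55), sulp-5 (-3.30) and the malonyl-CoA decarboxylase mlcd-1 (-3.09). Of the proteasome genes 7 were called higher and 31 adjusted over the list alone (median 1.00), such as pas-2 (1.27), pas-5 (1.24), pbs-6 (1.04) and pbs-1 (1.01). Of the translation genes it was 7 and 33 (median 0.81), such as eif-3.C (1.70) and the asparaginyl-tRNA synthetase nars-1 (1.35). At this time 352 probe sets were called, 172 higher and 180 lower, with 5303 at an unadjusted p under 0.05. The recomputed test called 0 at 6 h as well. Of the leading genes 8 of 12 were not detected in the lower condition.

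At 12 h the largest differences in fed larvae were in cuticle and moulting genes. The collagen sqt-1 was at 3936 ± 369 in fed and 10.2 ± 7.78 in starved larvae, a log2 difference of 8.59 ± 1.11, followed by mlt-11 (7.43 ± 1.84), the collagen dpy-5 (7.42 ± 0.51), mlt-8 (7.33 ± 0.85), the galactofuranose synthesis gene glf-1 (7.08) and dbd-8 (6.89). Lower in fed larvae were spig-15 (-6.19 ± 0.64), acs-2 (-5.46), the collagen col-80 (-5.42), far-7 (-5.25), cpr-2 (-5.23) and clec-15 (-4.41). Of the moulting genes 19 were called higher and 2 lower (32 and 3 adjusted over the list alone; median 1.88). Of the collagens 24 were higher and 2 lower (31 and 2 adjusted over the list alone; median 0.67), including rol-6 (6.72) and dpy-7 (6.36). Proteasome genes had 24 of 33 members higher (32 adjusted over the list alone; median 1.38) and heat shock genes 9 (15 adjusted over the list alone; median 0.90), such as hsp-60 (2.32), hsp-4 (2.16) and the protein disulfide isomerase pdi-2 (2.52). Fatty acid synthesis went the other way, with 10 members lower and 1 higher (12 and 4 adjusted over the list alone; median -0.84): the desaturases fat-3 (-2.25) and fat-4 (-2.17) and the acetyl-CoA carboxylase pod-2 (-1.69) were lower and fat-7 (3.76) higher. Of the DAF-16 list 7 were lower and 0 higher (16 and 0 adjusted over the list alone), such as aqp-1 (-3.45), nnt-1 (-3.21), sod-3 (-3.12) and the ferritin ftn-1 (-1.86). Ribosome biogenesis genes split, with fib-1 (1.15) among 6 higher and lpd-7 (-1.43), byn-1 (-1.25) and nst-1 (-1.23) among 4 lower. The deposited p-values called 2230 probe sets, 1035 higher, 1194 lower and 1 with equal means. The authors did not detect 11 of the 12 leading genes in the lower condition.

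At 15 h the leading genes in fed larvae were ilys-5 (7.18 ± 1.35), abu-7 (7.17), grl-21 (7.09), abu-15 (6.66), srlf-34 (6.37) and grd-14 (6.26). The lowest were hil-1 (-4.64 ± 0.29), far-7 (-4.26), dlhd-1 (-3.96), clec-76 (-3.58), the chemoreceptor-like srbc-20 (-3.58) and the bestrophin best-18 (-3.49). Histones had 3 members called higher and 0 lower (20 and 2 adjusted over the list alone; median 0.95), including his-15 (1.97), his-62 (1.64) and his-60 (0.99). The DNA replication list had a median of -0.35 with 0 members called by the deposited p-values. Desaturases fat-3 (-2.78) and fat-4 (-2.31) stayed lower and fat-7 (3.83) higher. The insulin-like gene daf-28 was higher (2.07 ± 0.41), and the antimicrobial peptide genes nlp-30 (3.09) and nlp-31 (2.12) were higher. In all, 1058 probe sets were called, 494 higher and 564 lower, with 5556 at an unadjusted p under 0.05, and the recomputed test called 623. Of the 12 leading genes 10 were not detected in the lower condition.

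At 24 h lep-5 (7.19 ± 0.34), ilys-5 (7.16 ± 0.58), irg-4 (6.80), sqt-1 (6.77), dpy-5 (6.76) and irg-5 (6.47) were highest in fed larvae relative to starved larvae. The lowest were hil-1 (-5.55 ± 0.36), far-7 (-5.25), clec-15 (-5.24), amt-1 (-5.14), clec-61 (-4.30) and acs-2 (-4.18). Of 13 heterochronic genes 2 were higher, lin-42 (4.55 ± 0.67) and dre-1 (0.76 ± 0.13), which had also passed at 12 h (0.96), and the Hunchback-like repressor hbl-1 was lower (-1.25 ± 0.32). The cell cycle gene cki-1 was lower (-0.71 ± 0.12). Germ line markers had 3 of 20 members higher (5 adjusted over the list alone; median 1.29), glh-1 (2.97), pgl-3 (1.86) and him-3 (1.76). Neuronal markers had 4 of 17 members lower (6 adjusted over the list alone; median -0.65), including egl-21 (-1.69) and egl-3 (-1.59), which process neuropeptides. Autophagy genes had 7 lower and 0 higher (12 and 0 adjusted over the list alone; median -0.86), led by lgg-2 (-2.31). Digestive enzymes had 6 members higher and 1 lower (8 and 4 adjusted over the list alone; median 0.45), with pcp-2 (5.86) and the cathepsin B-like cpr-5 (5.80) highest. Intestinal markers had 3 members higher and 0 lower (7 and 0 adjusted over the list alone; median 0.90), including the peptide transporter pept-1 (3.02). Calls numbered 1755, 872 higher, 882 lower and 1 with equal means, with 6180 at an unadjusted p under 0.05. For 10 of the 12 leading genes the probe set was not detected in the lower condition.

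Calls at 3 h and later overlapped mostly in the same direction, while the 1 probe set called at 1 h was called at 24 h with the opposite sign. Of the probe sets called at 12 h and at 24 h, 739 were shared, 737 of them with the same sign, where 174 would be shared by independent lists. For 12 h and 15 h 489 were shared, 489 with the same sign (105 for independent lists), for 15 h and 24 h 419 and 419 (82.3), for 6 h and 12 h 184 and 184 (34.8), and for 3 h and 6 h 38 and 38 (3.62). The times did not share conditions, but fed and starved arrays lay on different hybridization days at every time, so the lists were not independent. The values for independent lists also count all probe sets, detected or not.

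**Figure D2:**
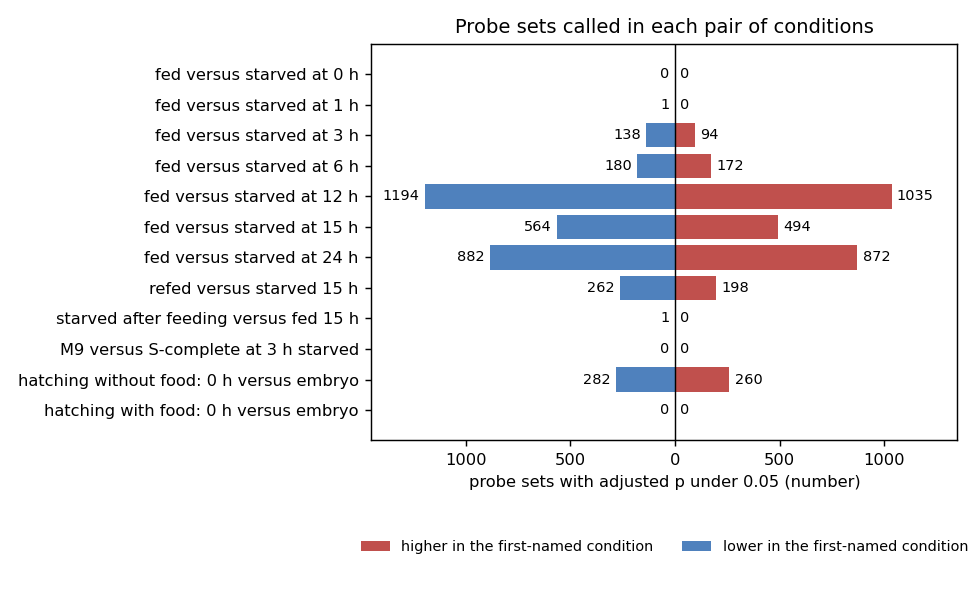
Number of probe sets called higher or lower, from the authors' deposited p-values adjusted here, in each of the 12 pairs of conditions. The counts for fed against starved larvae were 0, 1, 232, 352, 2230, 1058 and 1755 at 0, 1, 3, 6, 12, 15 and 24 h.

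**Figure D3:**
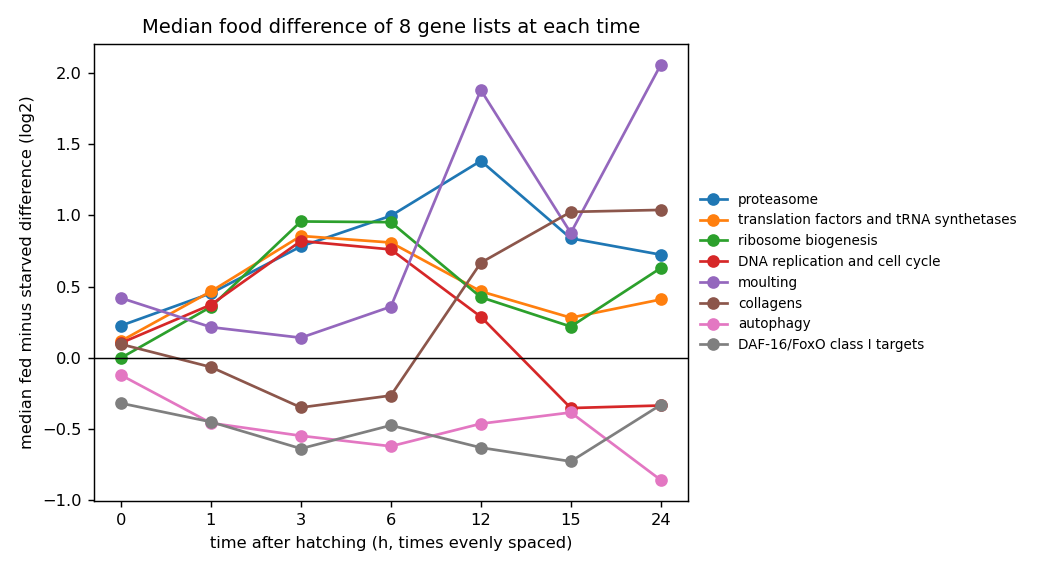
Median log2 fed minus starved difference of 8 gene lists at the 7 times, with times evenly spaced on the horizontal axis. The moulting median was 1.88 at 12 h and 2.06 at 24 h, and the DNA replication median went from 0.82 at 3 h to -0.35 at 15 h.

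Larvae starved for 12 h and then fed for 3 h were compared with larvae starved for 15 h. Refed larvae had lower acdh-1 (-5.58 ± 0.49) and hphd-1 (-3.98 ± 0.30), enzymes of propionate breakdown, lower hacd-1 (-4.41 ± 0.30), a hydroxyacyl-CoA dehydrogenase, and lower fmo-2 (-3.95), poml-4 (-3.79) and slc-36.5 (-3.78). The level of acdh-1 was 35.5 in refed larvae, 1702 in larvae starved for 15 h and 2831 in larvae fed for 15 h. Higher were ugt-22 (5.84 ± 1.03), the myo-inositol transporter hmit-1.1 (4.15), the glutathione transferase gst-24 (3.92), the carnitine palmitoyltransferase cpt-5 (3.78), lips-10 (3.77) and irg-8 (3.66). Ribosome biogenesis genes had 8 of 30 members higher and 0 lower (23 and 0 adjusted over the list alone; median 1.31), including nol-58 (2.26), lpd-6 (2.00), nol-14 (1.88) and the pseudouridine synthase dkc-1 (1.66). Translation genes had 8 of 57 higher and 0 lower (32 and 1 adjusted over the list alone; median 0.88), including inf-1 (2.00) and eif-3.C (1.67). Genes of the glyoxylate cycle, gluconeogenesis and trehalose had 5 members lower and 0 higher (12 and 3 adjusted over the list alone; median -0.76), including tps-1 (-1.91), tps-2 (-1.49), the trehalase tre-3 (-1.58) and the phosphoenolpyruvate carboxykinase pck-2 (-1.05). The fatty acid synthase fasn-1 was higher (1.65) and aqp-1 lower (-3.25). DNA replication genes had a median of 0.65 with 0 members called by the deposited p-values, over all genes and adjusted over the list alone. With the deposited p-values 460 probe sets were called, 198 higher and 262 lower, with 4935 at an unadjusted p under 0.05. Against larvae starved for 12 h they called 724, and against larvae fed from hatching for 3 h they called 0, with 2218 at an unadjusted p under 0.05.

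Removing food for 3 h after 12 h of feeding gave few calls. Against larvae fed for 15 h, the P-glycoprotein transporter gene pgp-1 was lower by -2.49 ± 0.62, from 78.1 to 13.9, a level the authors did not detect. It was the 1 probe set called by the deposited p-values, with 2187 at an unadjusted p under 0.05, and the recomputed test called 0. Some genes with higher means in starved larvae had positive differences that did not pass: nnt-1 2.49 ± 0.25, mtl-1 1.98 ± 0.26, fmo-2 1.88 ± 0.57, adh-1 1.56 ± 0.36, hil-1 1.07 ± 0.36 and icl-1 0.82 ± 0.21, while others lay within 1 error of 0, such as sod-3 (0.66 ± 0.82) and acs-2 (-0.28 ± 0.39). The differences of daf-28 (-1.90 ± 0.39) and fat-7 (-1.06 ± 0.29) were negative and did not pass. The median of ribosome biogenesis genes was -0.61, with 0 members called over all genes and 10 lower adjusted over the list alone, and that of translation genes was -0.26, with 0 called and 8 lower adjusted over the list alone. Heat shock (-0.56), pharynx (-0.54) and insulin-like genes (-0.29) lay below random lists and autophagy (0.33), moulting (0.43) and collagen genes (0.42) above them. Against larvae fed for 12 h the deposited p-values called 6 probe sets, and against larvae starved for 3 h after hatching 1353, 691 higher, 661 lower and 1 with equal means.

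The 2 switches were compared with the standing food difference at 12 h, with which they shared no condition. Across 22548 probe sets the refed minus starved 15 h difference correlated with the fed minus starved 12 h difference with a Pearson r of 0.499 and a Spearman rho of 0.504, and 68.2% of probe sets had the same sign (87.7% of the 2230 called at 12 h). The starved-after-feeding minus fed 15 h difference had an r of -0.00967 and a rho of 0.0868 with the starved minus fed 12 h difference, and 53.9% had the same sign (60.9% of those called). Fed larvae themselves changed between these times, with a moulting list median of -0.47 from 12 to 15 h. The low r therefore does not show that starving after feeding left the food difference unmoved. Genes are not independent replicates, so no p is given. With the 15 h conditions as the reference, which share a condition with each switch, the values were 0.510 and 0.229. Unchanged conditions simulated with the shared one gave 0.591 and 0.459, and the covariances were 0.390 and 0.0965 beside simulated covariances of 0.206 and 0.145. The simulated noise had no floor, unlike the data, and was wide near background. The simulated values therefore cannot serve as chance values, and this comparison decides nothing. The arrays of both switched conditions were hybridized on 1 day of their own.

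In starved larvae at 3 h, those in M9 buffer had much lower means for a small set of genes than those in S-complete. By size, fmo-2 was lower by -6.19 ± 1.05, acs-2 by -5.67 ± 0.97 on the probe set with the larger difference and -5.31 ± 0.74 on the other, adh-1 by -3.46 ± 0.34, the fatty acid elongase elo-5 by -3.14 ± 0.56, the phosphoglycolate phosphatase-like pgph-1 by -2.61 and hacd-1 by -2.44. The isocitrate lyase gene icl-1 (-1.49 ± 0.27) and acs-19 (-1.56 ± 0.25) had negative differences too. Other genes high in starved larvae differed by less than 2-fold between the media, such as far-7 (-0.37 ± 0.12), hil-1 (-0.23 ± 0.15), cpr-2 (-0.14 ± 0.46), mtl-1 (0.34 ± 0.18) and nnt-1 (0.00 ± 0.14). Upward differences were small, with cdr-1 at 1.23, the protein kinase A catalytic subunit kin-1 at 1.06, the tropomyosin lev-11 at 1.02, sup-26 at 1.01, ceh-22 at 0.95 and pho-9 at 0.94. Of these 12 leading genes by size, 7 were not detected in the lower condition. The authors' deposited p-values called 0 probe sets, with 718 at an unadjusted p under 0.05, and the recomputed test called 0. List medians lay between -0.17 for glyoxylate and trehalose genes and 0.24 for heterochronic genes. The array files mark the 3 M9 arrays with the sign of fed cultures, while the GEO title says no food, which was followed. They were run on the same 3 days as the fed arrays and shared 0 days with the starved S-complete arrays.

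Larvae that hatched without food were compared at 0 h with the embryo. The collagens col-98 (5.61 ± 0.54) and col-103 (4.98 ± 0.44), adh-1 (5.50 ± 1.06), spig-15 (5.05), the aldehyde dehydrogenase alh-5 (4.50) and the lipid binding protein gene lbp-2 (4.34) were higher. Lower were dbd-14 (from 1197 to 74.7), the cuticulin-like cutl-5 (-3.91), idpp-10 (-3.81), the trehalase tre-5 (-3.79), bli-5 (-3.76) and lips-7 (-3.59). Fatty acid synthesis genes had 2 of 20 members higher and 0 lower (13 and 0 adjusted over the list alone; median 1.03), the desaturase fat-6 (4.28) and the elongase elo-1 (2.17). DAF-16 targets had 2 members higher and 0 lower (8 and 0 adjusted over the list alone; median 1.00), adh-1 and dod-3 (2.44). Digestive enzymes had 3 and 0 (16 and 2; median 0.83), asp-8 (4.05), asp-14 (2.48) and cpr-4 (1.57). Ribosome biogenesis genes had 7 members higher and 0 lower (17 and 0 adjusted over the list alone; median 0.71), such as nol-6 (1.40) and lpd-7 (0.90). Moulting genes had 1 higher and 4 lower (2 and 8 adjusted over the list alone; median -0.94), including ptr-3 (-2.50) and grd-5 (-1.85). Neuronal markers had 1 lower, unc-119 (-0.93), and 0 higher (9 and 1 adjusted over the list alone; median -0.82). The deposited p-values called 542 probe sets, 260 higher and 282 lower, with 5716 at an unadjusted p under 0.05. For 11 of the 12 leading genes the probe set was not detected in the lower condition.

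Larvae that hatched with food had no probe set called relative to the embryo. By size, txt-4 (4.34 ± 1.13), ugt-66 (4.09), srlf-34 (4.06), ugt-8 (3.99), adh-1 (3.86) and spig-15 (3.86) were higher and wrt-8 (-5.45 ± 1.22), lrx-1 (-3.90), clec-230 (-3.86), ptr-16 (-3.83), nas-12 (-3.78) and idpp-10 (-3.65) lower. The authors detected none of these 12 genes in the lower condition, and adh-1, spig-15 and idpp-10 were also among the leading genes without food. Fatty acid synthesis genes had a median of 1.25 (0 called over all genes, 11 higher adjusted over the list alone), lysozymes 0.83, ribosome biogenesis genes 0.71 and intestinal markers 0.68. Pharyngeal (-0.83), neuronal (-0.78) and moulting genes (-0.51) lay below random lists. The deposited p-values called 0 probe sets, with 3656 at an unadjusted p under 0.05, and the recomputed test called 0. Embryo arrays were hybridized on the days of the starved arrays.

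Over time, levels moved more in fed than in starved larvae. In fed larvae the collagen col-41 spanned a log2 range of 9.60 between 3 h (5 ± 4.74, the floor) and 12 h (3875 ± 298), and sqt-1 (8.45), rol-8 (8.23), lips-6 (8.03), lgc-22 (7.51) and dpy-5 (7.31) were also higher at a later time. The collagens col-74 (6.14) and col-165 (5.81), gmap-3 (5.81), mtre-1 (5.74), nas-30 (5.63) and cut-3 (5.59) were higher at an earlier time. In starved larvae acs-2 spanned 8.43, from 10.1 at 0 h to 3465 at 6 h, and cpr-2 (6.45), hacd-1 (5.86), clec-47 (5.85), the enoyl-CoA hydratase ech-7 (5.56) and elo-5 (5.34) were higher later. In the other direction fipr-22 (6.57), pqn-71 (6.29), pcp-2 (6.24), grl-21 (6.22), rips-1 (6.04) and fipr-23 (5.94) were higher earlier. Of 13912 probe sets detected in fed larvae 5996 (43.1%) had a range of at least 2-fold, against 3045 of 13150 (23.2%) in starved larvae, and the range was larger in fed larvae for 72.5% of the 14507 detected in either. The authors did not detect the lowest time for any of the 24 genes named here, so their ranges rest on levels near background and are lower bounds where the mean was at the floor. The median log2 range was 0.89 in fed and 0.59 in starved larvae. None of the authors' analyses of variance tested time within a food state, so these ranges carry no test. Between neighbouring times the deposited pair tests called 56 probe sets for fed 12 h against 6 h (39 higher, 17 lower) and 2 for fed 15 h against 12 h. They called 0 for each other neighbouring pair, fed or starved, with 606 to 2539 probe sets at an unadjusted p under 0.05 in starved larvae and 948 to 2752 in fed larvae. Over all conditions of the 2-factor analysis, the authors' deposited table, adjusted here, called 15198 of 22055 probe sets for nutrition, 13413 of 22176 for time and 12054 of 22040 for food by time, and a 1-factor analysis called 15933 of 22268.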

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

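Of the tests in this part, those of the larval stage and of food for the 0 h pattern were fixed before the values were seen, and the other 8 were chosen after the result was seen.

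A difference between groups set apart 12054 probe sets past the food by time test of the authors' deposited table, adjusted here. The same kind of difference, a slope of the list in the fed minus starved difference with time, set apart 14 lists by camera. The median slope per unit of log2(h + 1) was 0.368 for moulting, 0.265 for collagens, 0.196 for fatty acid oxidation, 0.164 for lysozymes, 0.152 for the proteasome, 0.124 for digestive enzymes, 0.11 for heat shock genes, 0.0876 for heterochronic genes, 0.0451 for detoxification and 0.0115 for cytosolic ribosomal proteins. It was -0.232 for fatty acid synthesis, -0.131 for neurons, -0.123 for DNA replication and -0.101 for autophagy. With an estimated correlation none of the 14 passed. A further flag fell on the 1939 probe sets without a gene mapping, which were tested with the others but could not be named. Between fed and starved larvae at 12 h 159 of them were called, 62 higher, 96 lower and 1 with equal means. That was 8.2% of the 1939, against 9.89% of all probe sets, and 0 of the 1939 were called between M9 and S-complete.

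Fed and starved arrays were hybridized on different days, so the day might account for the 6831 calls of the 7-time comparison. The M9 arrays held starved larvae per the GEO titles, though the array files mark all 3 with the sign of fed cultures, and were run on the days of the fed arrays; if the day were the whole cause, or if they held fed larvae, their difference from starved S-complete larvae would follow the food difference with a slope near 1. The slope was 0.0614, which argues against both as the whole cause over these probe sets together but leaves a part of the day open. Its interval of 0.0462 to 0.0776 came from resampling probe sets, which are not independent, and holds no spread between cultures or days. The medium differed along with the day, so the slope does not isolate the day. It also does not speak for single genes. In fed 3 h minus M9 3 h larvae, on shared days, 18 of the 20 named genes kept their sign. The others, fmo-2 (2.34 ± 1.16) and adh-1 (0.14 ± 0.38), did not, so day or medium stayed open for them. Food could not be settled by the switches. The refed minus starved 15 h difference correlated with the food difference at 12 h with an r of 0.499, but starving after feeding gave -0.00967. Both differences behind the first value set arrays of the starved days against other days. The second value rests on fed larvae at 12 and at 15 h, between which the moulting list changed by a median of -0.47. Its low r therefore decides nothing against food. Of the 64 ways to exchange fed and starved within times, 1, the real one, gave as many calls, and the highest other gave 3; for the slope with time 4 gave as many as the real 1214, the highest 3672, but exchanging the earliest times turns a standing food difference into a slope, so this test is void.

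M9 larvae had low means of a few genes that were high in starved S-complete larvae, among them acs-2 and fmo-2. If the M9 arrays had held fed larvae, the other genes lower in fed larvae would be low as well, but their median was -0.0394 against -0.603 in fed larvae at 6 h, a ratio of 0.0653, which argues against it. Of the 60 low probe sets 57 (95%) were also lower in fed than in starved larvae at 6 h, a pair that shares no condition with M9, against at most 76.7% in 10000 random sets matched on level, which argues against array error as the whole cause. The low probe sets had a median of -1.48 in fed minus starved larvae at 3 h, which shares the starved 3 h condition, and of -1.63 at 6 h, so the medium, possibly through a component of S-complete that starved larvae respond to, could not be separated from the day of hybridization. The labels do not state how S-complete was prepared.

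Fed larvae at 0 h were closer to the embryo than starved larvae at 0 h. The embryo also correlated more with fed than with starved larvae at every later time, such as 0.903 against 0.848 at 15 h and 0.871 against 0.837 at 24 h. The pattern was therefore not particular to 0 h. A shared hybridization day would bring the embryo closer to the starved larvae, whose days it shared, so the pattern itself (r higher with fed larvae by 0.0326, 0.951 against 0.918) runs against the day and no separate test was made. An earlier stage of the fed larvae was tested at 0 h alone and may account for the pattern at that time. Over 1093 probe sets the mean change from the embryo was 1.39 in fed and 1.74 in starved larvae. The ratio of 0.795 met the criterion fixed beforehand, a ratio under 0.8, but only narrowly. Its interval over resampled probe sets, 0.780 to 0.809, reached past 0.8, so this could not be told. The requirement on the interval was added after the value was seen. Food stayed open: the 0 h difference correlated less with the food difference at 6 h (0.347) than with the difference between embryo and starved larvae at 1 h (0.660), a difference of -0.314, but the pattern itself fixes the second value, so this excludes nothing.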

How the results depend on the processing

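The alternatives were chosen before the data were examined, and the cause of each change below was not tested. Over all comparisons 352 values stayed the same, 46 moved, 23 became weaker and 1 reversed; among list medians 1495 stayed the same, 36 became stronger, 32 weaker and 3 reversed; among single genes 987 stayed the same, 24 became stronger and 49 weaker. At an adjusted p under 0.05 the count of the 7-time comparison lay between 4756 and 6878; no stricter threshold was run for it. The floor at the 10th percentile equalled the deposited floor of 5 and so moved nothing. No paired analysis was possible between culture series because the tables hold means per condition and no values per array; fed and starved were paired by time. Levels near background limit the size of a difference where a condition was not detected. In each condition 10.4% of values or more stood at the floor.

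With each time left out, the growth count ranged from 26 to 764 (1214 with all times), the adjusted p of neurons from 0.0162 to 0.0607 and that of pharynx from 0.0132 to 0.124. With linear hours the growth count was 1964. At an unadjusted p under 0.01 the counts were 252 at 0 h, 998 at 1 h, 1951 at 3 h, 2281 at 6 h, 2539 at 15 h, 2889 at 24 h, 2095 for refed, 550 for starved after feeding, 138 for M9, 2440 for hatching without food and 1156 with food. At an adjusted p under 0.01 they were 0 at 1 h, 1 at 3 h, 0 at 6 h, 93 at 12 h, 25 at 15 h, 2 at 24 h, 1 for refed, 0 for starved after feeding and 0 for hatching without food. Over detected probe sets they were 8 at 1 h, 971 at 3 h, 1790 at 6 h, 3524 at 12 h, 2363 at 15 h, 3054 at 24 h, 1472 for refed and 1891 for hatching without food. With recomputed p-values they were 0 at 1 h, 0 at 3 h, 0 at 6 h, 623 at 15 h and 0 for starved after feeding. At 2-fold or more they were 146 at 3 h, 208 at 6 h, 1447 at 12 h and 697 at 15 h.

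Over detected probe sets the r of refeeding was 0.568, the adjusted p was 0.172 for cytosolic ribosomal proteins and 0.0636 each for germ line, neurons and pharynx, and the early embryo median at 0 h reversed to -0.0289. With the 15 h reference, which shares a condition, the r of starving after feeding reversed to 0.229. With an estimated correlation the adjusted p was 0.083 for DAF-16 targets, 0.742 for DNA replication and for collagens, 0.44 for autophagy, cytosolic ribosomal proteins, glyoxylate genes, heat shock, proteasome and translation, 0.715 for germ line, neurons and pharynx, 0.587 for histones and ribosome biogenesis and 0.582 for moulting. With quantile normalization the cytosolic ribosomal list had an adjusted p of 0.525, and its medians at hatching reversed to 0.0705 without and 0.0691 with food.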

Other observations

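In fed larvae, means of moulting genes were lower at 15 h than at 12 and 24 h, while the sample titles go from L1 at 12 h to L1 to L2 at 15 h and L2 at 24 h. The Period homologue lin-42 stood at 245, 71.9 and 195 at 12, 15 and 24 h, mlt-10 at 409, 44.5 and 209 and the collagen dpy-7 at 627, 47.1 and 657. Not all cuticle genes followed: the median of the collagen list was 0.19 from 12 to 15 h (mean -0.03) and -0.11 from 15 to 24 h (mean 0.08), opposite to dpy-7. The median of the moulting list was -0.47 from 12 to 15 h and 0.48 from 15 to 24 h, with hypodermal markers at -0.67, DNA replication genes at -0.48, the proteasome at -0.37, histones at 0.41 and pharyngeal markers at 0.53 in the first interval, and germ line markers at 0.72, digestive enzymes at 0.52, fatty acid synthesis genes at 0.41, histones at -0.40, neuronal markers at -0.48 and pharyngeal markers at -0.55 in the second. Of single probe sets the authors' deposited table, adjusted here, called 2 between 12 and 15 h and 0 between 15 and 24 h, with 2781 and 2752 at an unadjusted p under 0.05.

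Larvae refed for 3 h after 12 h of starvation were set beside larvae fed for 3 h from hatching, on arrays of different days. The deposited pair test called 0 probe sets, with 2218 at an unadjusted p under 0.05. Early embryo markers (0.83, with 8 of 15 detected in any condition), germ line markers (0.69), heat shock (0.44), translation (0.36) and proteasome genes (0.36) had higher medians in refed larvae, and pharynx (-0.87), collagens (-0.69), body wall muscle (-0.65) and lysozymes (-0.65) lower ones. In starved larvae from 0 to 24 h the medians were 1.42 for fatty acid synthesis and 0.62 for histones, and -1.53 for pharynx, -1.19 for body wall muscle and -1.12 for collagens.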
